A study of Mus musculus with 14 samples.

How the data were processed

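Total RNA was profiled on mouse Illumina bead arrays in 14 tissue samples from BALB/C mice aged 8 weeks. Per the labels, 3 samples were control tissue, 6 were tumor microenvironment tissue taken on day 4 after tumor inoculation, and 5 were taken on day 14. The tumor was AB1, a mouse malignant mesothelioma line. Per the labels, tissue was lysed in a Tissue Lyser, RNA was extracted with Trizol and cleaned on RNeasy columns with DNase I, quality was checked on a Bioanalyser, and biotin-labelled cRNA was made with the Ambion MessageAmp kit. The organ or site of the control tissue, the chip that held each array, and whether each array came from a separate animal are not given in the sources used here. The p-values therefore measure only the spread between these samples.

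The deposited table of unnormalized values holds a bead-averaged intensity for each of 45281 probes on each array, on a linear scale and without background subtraction. Per the file headers, it also holds a detection p-value for each probe and array, which measures the probe against the negative controls of that array and moves in steps of 1 in 936. It has no rows for control probes and no gene names. The second deposited table holds log2 values made by the authors for 7016 probes. Tested on the values, these are exactly the probes with detection p under 0.05 on at least 2 of 3 control, 4 of 6 day 4 and 4 of 5 day 14 arrays, and the values are the quantile-normalized log2 raw intensities of that subset. The deposited tables carry the names of control replicates 1 and 2 the other way round: each raw column correlated at 0.999 with the normalized column of the other name, and at 0.972 and 0.971 with its own. Both are control arrays, so no group changed, and arrays are named here as in the raw table.

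Gene names came from the annotation supplied for the 7016 probes. Of these, 6083 matched 1 gene, 3 matched several and 930 matched none; 6075 of the symbols were looked up by gene ID in a table of mouse genes, which changed 0 of them. After keeping 1 probe per gene, the probe with the highest mean over all 14 arrays, 5033 genes were tested, and 903 of them had several probes. The authors' detection rule asks for signal in all 3 groups, so a gene that missed it in any group has no name here. Such genes, among them any detected at day 4 and day 14 but not in control tissue, were not analysed by name. No coordinates are given, because no genome build is given in the sources used here.

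Raw intensities were background-corrected with normal-exponential convolution fitted to the detection p-values, with an offset of 16, then quantile-normalized between arrays and put on the log2 scale (neqc in limma 3.58.1, R 4.3.3, statmod 1.5.0). Probes with detection p under 0.05 on at least 3 arrays were kept, 14916 in all. A linear model with 3 groups was fitted to all 14 arrays with limma's lmFit and eBayes at their default settings. The 3 contrasts were day 4 minus control, day 14 minus control and day 14 minus day 4. All tests were two-sided, p-values were adjusted with the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p under 0.05. A count at an absolute log2 difference of 1 or more stands beside each count. Standard errors come from the limma fit, and standard deviations are over the arrays of a group.

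The groups, tests, gene lists and the rule for named genes were set before the data were examined. Of 38 gene lists for pathways, cell types and tissues, 21 had at least 5 measured members and were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. The other 17 had fewer, and the natural killer cell list and the B cell and plasma cell list had 0. Camera with a correlation estimated from the data, and fry, which asks whether a list's genes move on balance in 1 direction without comparing them with other genes, were run as alternatives. The genes named in each comparison were the 4 with the largest rise and the 4 with the largest fall among called genes whose groups did not overlap, leaving out clone and predicted names. To these were added the 2 members with the smallest p in each of the 8 lists with the smallest camera p, the member with the smallest p in each other list, and a fixed set of sentinel genes. The sentinels Cd8a, Gzmb, S100a8, Mki67 and Msln had no named probe and were not analysed here. Stab1, Tgm2, Serpina3b, Timp3, Lce1c, Clec10a, Mgl2, Ldha, Tpi1, P4ha2, Cd163 and Gpnmb were in part named after their values were seen, to complete counts or to describe genes that moved in opposite directions.

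Array quality was described by the share of probes with detection p under 0.05, compared between groups with an exact permutation test. The number of arrays limits the precision. The model was tested on simulated data made with the group sizes and 5033 genes of each comparison. For day 4 against control it recovered 14.9% of genes planted at a log2 change of 0.5, 74.6% at 1 and 100% at 2, with 5 false calls among 144. For day 14 against control the shares were 14.9%, 79.1% and 100%, with 9 false calls among 153. For day 14 against day 4 they were 23.9%, 79.1% and 100%, with 9 false calls among 159. A planted list was called in each comparison, and 0 of 20 unchanged lists were. The simulated genes varied independently of each other, whereas correlations estimated in the real lists ran from 0.083 to 0.79. The simulation therefore does not show how often camera at the preset correlation calls unchanged lists of correlated genes.

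Alternatives covered background correction, between-array normalization, the authors' values, the filter on dim probes, the choice of probe, the arrays in the fit, the variance model, array weights, the replicate number as a block, the threshold, and leaving out each array in turn. Added alternatives, chosen after seeing the data, left out the 2 dimmest arrays, used the share of detected probes as a covariate, or scaled the arrays over the probes detected on all of them. Overlap between the contrasts with control was set against 100 simulations in which the residuals of the arrays were reassigned around unchanged groups and the same 3 control arrays served both contrasts.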

Results

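The samples fell into 3 control arrays, 6 arrays of AB1 tumor microenvironment tissue at day 4 and 5 at day 14. The share of probes detected was 25.1% ± 1.37 (SD, n = 3) in control tissue, 23.3% ± 3.88 (SD, n = 6) at day 4 and 24.3% ± 6.32 (SD, n = 5) at day 14. These shares did not pass a two-sided exact permutation test in any of the 3 comparisons (p = 0.512 for day 4 against control, p = 0.875 for day 14 against control and p = 0.766 for day 14 against day 4). Single arrays ranged from 15.6% in day 14 replicate 5 to 30.6% in day 14 replicate 2. Control tissue carried high signal for skin, hair and muscle genes. Its mean log2 intensity was 12.48 ± 0.31 (SD, n = 3) for Krt14, the keratin of basal epidermis, 12.49 ± 0.42 for Krt27, a keratin of the inner root sheath of the hair follicle, and 11.54 ± 0.86 for Acta1, skeletal muscle actin. Below, values after ± are standard errors of a log2 difference unless marked SD. A list's average is the mean log2 difference of its measured members, with its camera p beside it.

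The first comparison asked how tissue at day 4 after inoculation differed from control tissue. Its largest changes, among called genes whose groups did not overlap, were the falls of Krt27, Gjb2, Chac1 and Lrrc15. Krt27 fell 145-fold (log2 difference -7.18 ± 0.34, adjusted p = 1.0e-10), to a mean log2 intensity of 5.31 ± 0.76 (SD, n = 6), with all 6 day 4 arrays below the 3 controls. Gjb2, which encodes the gap junction protein connexin 26, fell 36.9-fold (-5.20 ± 0.40). Chac1, a glutathione-degrading enzyme of the stress response, fell 25.3-fold (-4.66 ± 0.22), and Lrrc15, a leucine-rich repeat membrane protein, fell 17.8-fold (-4.15 ± 0.48). Among the genes that rose, Ttn, the giant elastic protein of the sarcomere, was 5.84-fold higher (2.55 ± 0.37). Myh1, a fast myosin heavy chain, was 4.69-fold higher (2.23 ± 0.48), and Tcea3, a transcription elongation factor, 4.60-fold higher (2.20 ± 0.37). Pde4dip, a centrosome and Golgi scaffold protein, was 4.28-fold higher at its brightest probe (2.10 ± 0.60, adjusted p = 0.041), while its other 2 probes gave -0.02 and 0.05. All 6 day 4 arrays lay above the 3 controls for these 4 genes, as the rule that picked them required. Of the genes that fell, Krt27, Gjb2 and Lrrc15 were above background on 5 of 6 day 4 arrays and Chac1 on 4, so the sizes of their falls rest on the background correction. Without background correction the difference was -5.53 for Krt27 and -2.90 for Chac1.

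In the skeletal muscle list 13 of 22 measured members rose, 1 fell and 8 did not pass, and 19 rose when adjusted over the list alone. The list averaged 1.50 (adjusted p = 3.1e-10; adjusted p = 0.37 with an estimated correlation). Des, which encodes the muscle intermediate filament desmin, rose 3.64-fold (1.86 ± 0.34, adjusted p = 0.0025). The member that fell was Tpm1, a tropomyosin also made in many cells outside muscle (-1.24 ± 0.16, adjusted p = 8.3e-05). Acta1 had a difference of 1.12 ± 0.49 (adjusted p = 0.18). The list of hypoxia and glycolysis genes was higher beside the muscle list, with 5 of 12 members up in both adjustments and 7 not passing. The list averaged 0.50 (adjusted p = 0.0039; adjusted p = 0.37 with an estimated correlation). These were Pkm (1.11 ± 0.16), Gapdh (1.07 ± 0.25), Ldha (0.97 ± 0.27) and Tpi1 (0.75 ± 0.23), enzymes of glycolysis and lactate production, and P4ha2 (0.98 ± 0.27), a collagen prolyl hydroxylase. No member of the adipocyte list passed over all genes, but 4 of 9 were higher when adjusted over the list alone, and the list was higher as a set. The list averaged 0.55 (adjusted p = 0.0089; adjusted p = 0.37 with an estimated correlation). Adipoq, the fat hormone adiponectin, had a difference of 0.92 ± 0.35 (adjusted p = 0.12), Pnpla2, a triglyceride lipase, 0.64 ± 0.22 (adjusted p = 0.078), and Car3, a carbonic anhydrase abundant in fat and muscle, 1.10 ± 0.41 (adjusted p = 0.11).

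The monocyte and macrophage list and the lists of antigen presentation genes were higher at day 4. In the monocyte and macrophage list 1 of 12 members rose and 11 did not pass, with 3 higher when adjusted over the list alone. The list averaged 0.54 (adjusted p = 0.0012; adjusted p = 0.37 with an estimated correlation). The member was Ms4a6d, a macrophage membrane protein (0.99 ± 0.23, adjusted p = 0.014), while Adgre1, which encodes the macrophage marker F4/80, had 0.97 ± 0.42 (adjusted p = 0.18). The scavenger receptor gene Cd163 had 0.83 ± 0.26 (adjusted p = 0.058). For MHC class II presentation 1 of 9 members rose, 6 when adjusted over the list alone. The list averaged 0.65 (adjusted p = 0.0012; adjusted p = 0.37 with an estimated correlation). That gene was H2-DMb1, part of the chaperone that loads peptides on class II molecules (1.12 ± 0.25). Its paralog H2-DMb2 had 0.85 ± 0.28 (adjusted p = 0.072). For MHC class I presentation 2 of 12 rose, the class I chain genes H2-D1 (1.08 ± 0.21) and H2-T23 (0.79 ± 0.20), and 5 when adjusted over the list alone. The list averaged 0.41 (adjusted p = 0.0084; adjusted p = 0.37 with an estimated correlation). The interferon gamma response list was higher as a set with 0 of 9 members passing in either adjustment (mean 0.47, adjusted p = 0.015; adjusted p = 0.41 with an estimated correlation), and Irgm2, an interferon-induced GTPase, had 0.85 ± 0.33 (adjusted p = 0.12). In each of these 4 lists the mean of every day 4 array lay above that of every control array. The type I interferon list was not called with all arrays (1 of 6 rose in both adjustments; mean 0.49, adjusted p = 0.062). It was called without control replicate 3 (adjusted p = 0.049), day 4 replicate 2 (0.018) or 5 (0.026), or day 14 replicate 2 (0.043) or 5 (0.049). The member that rose was Eif2ak2, the double-stranded RNA sensor kinase (0.95 ± 0.25, adjusted p = 0.031). Complement was not called either (1 of 10 rose in both adjustments, adjusted p = 0.062), except without day 4 replicate 2 (0.037) or 3 (0.019), and the member was C2 (0.70 ± 0.21, adjusted p = 0.0497). The T cell gene Cd3e (0.31 ± 0.26, adjusted p = 0.54), the regulatory T cell factor Foxp3 (-0.17 ± 0.20, adjusted p = 0.68) and the arginine-degrading enzyme gene Arg1 (0.17 ± 0.19, adjusted p = 0.67) did not pass.

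Among stromal lists, blood vessel endothelium had 2 of 12 members higher, Plvap, of endothelial fenestrae (1.14 ± 0.23), and Mmrn2, an endothelial matrix protein (0.74 ± 0.22), with 3 when adjusted over the list alone. The list averaged 0.39 (adjusted p = 0.0089; adjusted p = 0.37 with an estimated correlation). Collagens and matrix had 2 of 18 higher, Col6a1 (1.08 ± 0.30) and Col1a1 (0.78 ± 0.23, adjusted p = 0.047), with 5 higher and 1 lower when adjusted over the list alone. The list averaged 0.43 (adjusted p = 0.013; adjusted p = 0.40 with an estimated correlation), and its call was lost without control replicate 1 (mean 0.23, adjusted p = 0.14). Neither the fibroblast list (1 of 9 rose in both adjustments, Vim at 0.77 ± 0.22; adjusted p = 0.12), the TGF-beta list (1 of 10 rose and 2 fell in both adjustments; average 0.01 but camera direction down, adjusted p = 0.99) nor the matrix remodelling list (0 of 13; adjusted p = 0.26, but 0.049 without control replicate 3) was called with all arrays. Tgfbi, a matrix protein induced by TGF-beta, rose by 1.13 ± 0.19. Epidermal keratinocyte genes were not called as a list with all arrays (3 of 14 rose, 4 higher and 1 lower when adjusted over the list alone; mean 0.35, adjusted p = 0.064). The list was called without control replicate 2 (adjusted p = 0.0499) or 3 (0.027), day 4 replicate 1 (0.0497), 5 (0.042) or 6 (0.045), or day 14 replicate 2 (0.044). Its mean ran from 0.19 without control replicate 1 to 0.47 without control replicate 3. Lce1c, of the late cornified envelope, rose by 1.54 ± 0.30, and Krt14 had 0.07 ± 0.21 (adjusted p = 0.89). The ribosomal protein list was lower, with all 6 day 4 arrays below the controls, 1 of 18 members falling and 0 when adjusted over the list alone (mean -0.34, adjusted p = 7.1e-04; adjusted p = 0.37 with an estimated correlation). Rpl27 had -0.69 ± 0.21 (adjusted p = 0.049) and Rps14 -0.58 ± 0.19 (adjusted p = 0.073). The immediate early and heat shock list was not called with all arrays, with 1 of 13 lower in both adjustments (mean -0.17, adjusted p = 0.12). It was called without day 4 replicate 3 (mean -0.25, adjusted p = 0.030). The list lay below the controls on 5 of 6 day 4 arrays and above them on 1. Cell cycle genes were lower as a set with 0 of 14 passing in either adjustment, 3 of 6 day 4 arrays below the controls, and Cdca8, a chromosomal passenger protein, at -0.86 ± 0.29 with adjusted p = 0.079. The list averaged -0.32 (adjusted p = 0.015; adjusted p = 0.41 with an estimated correlation), and its call was lost without control replicate 1 (mean -0.18, adjusted p = 0.16) or day 4 replicate 2 (mean -0.19, adjusted p = 0.071).

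In all, 404 of 5033 named genes changed at day 4, 234 higher and 170 lower, and 195 of them at least 2-fold (limma). The balance was the other way over all 14916 probes kept, 273 higher and 434 lower, since the probes without a gene name had 59 higher and 259 lower. The groups did not overlap for 13.9% of genes, where chance gives 2.38%. The count was 93 without control replicate 1, 31 higher and 62 lower, 184 without control replicate 2, and 255 without day 4 replicate 1 or day 4 replicate 5, and of 37 named calls the 13 for Ttn, Tcea3, Des, Pkm, H2-D1, Tgfbi, Tpm1, Krt27, Gjb2, Chac1, Lrrc15, Gpnmb and Ltf passed whichever array was left out. With the authors' values 183 genes were higher and 292 lower, median scaling, which put the median of all genes at -0.16, left 20 genes, all lower, and fry called 0 lists.

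**Figure D1:**
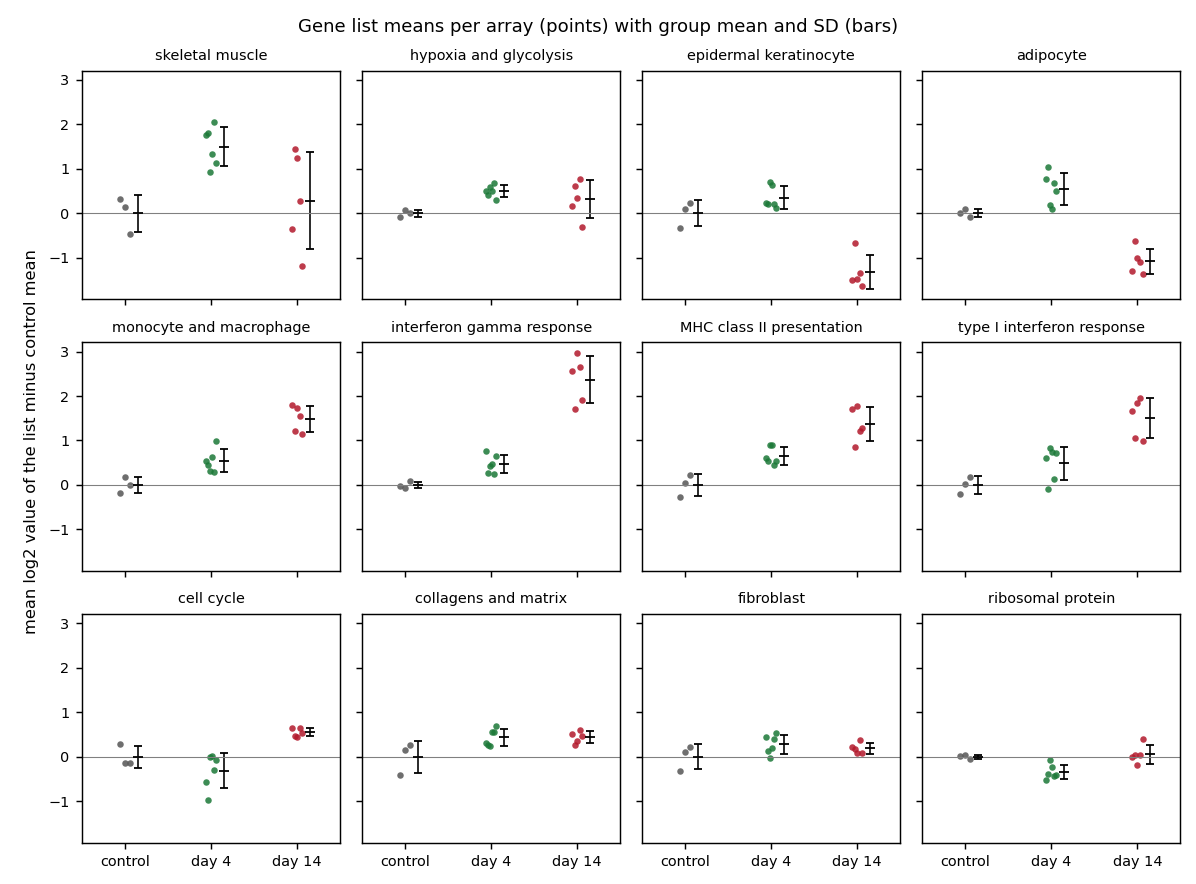
Mean log2 intensity of the members of 12 gene lists on each array, minus the control mean, on the vertical axis, for control, day 4 and day 14 arrays. Points are arrays and bars are group means with SD; the muscle list is highest at day 4, and the interferon gamma and macrophage lists are highest at day 14, when the epidermal and adipocyte lists lie below control.

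The second comparison, day 14 against control, had Cxcl9, Masp1, Timp1 and Igtp as its largest rises and Mgll, Casp14, Dct and Zfp750 as its largest falls, among called genes whose groups did not overlap. Cxcl9, an interferon gamma-induced chemokine that attracts T cells, rose 17.9-fold (4.16 ± 0.33, adjusted p = 4.8e-07), from a mean log2 intensity of 5.02 ± 0.11 (SD, n = 3) to 9.18 ± 0.72 (SD, n = 5). Masp1, a protease of the lectin pathway of complement, rose 9.18-fold (3.20 ± 0.26), Timp1, an inhibitor of matrix metalloproteinases, 8.97-fold (3.16 ± 0.26), and Igtp, an interferon-induced GTPase, 7.50-fold (2.91 ± 0.26). Mgll, a monoacylglycerol lipase, fell 4.76-fold (-2.25 ± 0.35), Casp14, a caspase of cornification, 4.23-fold (-2.08 ± 0.39), Dct, an enzyme of melanin synthesis, 3.99-fold (-2.00 ± 0.39), and Zfp750, a regulator of epidermal differentiation, 3.98-fold (-1.99 ± 0.34). For each of these 8 genes all 5 day 14 arrays lay on the same side of the 3 controls, as that choice required.

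In the interferon gamma response list 8 of 9 members rose, and 9 when adjusted over the list alone. The list averaged 2.36 (adjusted p = 1.0e-11; adjusted p = 0.057 with an estimated correlation). Gbp2, a guanylate-binding protein, rose 6.81-fold (2.77 ± 0.31) and the transcription factor Irf1 5.66-fold (2.50 ± 0.22). In the monocyte and macrophage list 10 of 12 rose, and 11 when adjusted over the list alone. The list averaged 1.49 (adjusted p = 1.8e-09; adjusted p = 0.057 with an estimated correlation). Ms4a6d rose 6.95-fold (2.80 ± 0.24), Aif1, a calcium-binding protein of macrophages, 6.58-fold (2.72 ± 0.27), and Adgre1 3.37-fold (1.75 ± 0.44). All 9 members of MHC class II presentation rose in both adjustments (mean 1.37, adjusted p = 1.3e-07; adjusted p = 0.079 with an estimated correlation), among them H2-DMb1 (1.59 ± 0.25) and Lgmn, a lysosomal protease (1.87 ± 0.32). Of MHC class I presentation 9 of 12 rose, and 11 when adjusted over the list alone (mean 1.07, adjusted p = 1.3e-07; adjusted p = 0.057 with an estimated correlation), including Psmb10, an immunoproteasome subunit (2.11 ± 0.22), and H2-T23 (1.35 ± 0.21). Type I interferon genes rose in 5 of 6 cases in both adjustments, with Oasl2 at 2.72 ± 0.36 and Eif2ak2 at 1.89 ± 0.26. The list averaged 1.50 (adjusted p = 5.0e-05; adjusted p = 0.11 with an estimated correlation). Complement rose in 4 of 10 in both adjustments, with the properdin gene Cfp at 1.54 ± 0.24. The list averaged 0.69 (adjusted p = 0.0083; adjusted p = 0.29 with an estimated correlation). Beside these lists, markers of other tissues moved the other way: the averages of the epidermal and adipocyte lists were lower on all 5 day 14 arrays than on any control.

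Of the epidermal keratinocyte list 13 of 14 members fell in both adjustments. The list averaged -1.33 (adjusted p = 2.8e-09; adjusted p = 0.082 with an estimated correlation). Krt15, a keratin of basal and bulge keratinocytes, fell 3.52-fold (-1.81 ± 0.26), Trp63, the master regulator of stratified epithelium, 3.27-fold (-1.71 ± 0.25), and Krt14 1.61-fold (-0.69 ± 0.21, adjusted p = 0.027). Krt27 fell too, but by 1.20 ± 0.35 (adjusted p = 0.021). Of the adipocyte list 7 of 9 fell, and 8 when adjusted over the list alone (mean -1.09, adjusted p = 1.3e-05; adjusted p = 0.10 with an estimated correlation), among them Scd1, a fatty acid desaturase (-1.72 ± 0.26), Dgat2, which completes triglyceride synthesis (-1.06 ± 0.20), and Adipoq (-1.27 ± 0.36). Skeletal muscle was not called with all arrays, with 0 of 22 members passing in either adjustment (mean 0.28, adjusted p = 0.34), and its arrays spread from below the controls to above them. The list was called without day 14 replicate 5 (mean 0.65, adjusted p = 0.0075), and its mean was -0.0042 without day 14 replicate 2, 0.05 without day 14 replicate 3 and 0.05 without control replicate 3.

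Cell cycle genes rose in 5 of 14 cases in both adjustments (mean 0.55, adjusted p = 0.0079; adjusted p = 0.43 with an estimated correlation), with Prc1, a protein of the dividing spindle, at 1.74 ± 0.38 and Cenpa, the centromeric histone, at 1.21 ± 0.28. Collagens and matrix had 5 of 18 higher in both adjustments (mean 0.43, adjusted p = 0.036; adjusted p = 0.43 with an estimated correlation), with the small proteoglycan Bgn at 1.71 ± 0.22 and Col1a1 at -0.34 ± 0.24 (adjusted p = 0.37). Matrix remodelling enzymes had 3 of 13 higher and 1 lower, with 5 higher and 1 lower when adjusted over the list alone. The list averaged 0.52 (adjusted p = 0.036; adjusted p = 0.29 with an estimated correlation). Timp1 and Lox, the collagen cross-linking enzyme (2.04 ± 0.33), were among those that rose, and the member that fell was Timp3 (-1.39 ± 0.29). TGF-beta genes were at the threshold (3 of 10 rose in both adjustments, among them the activin gene Inhba at 1.97 ± 0.26; adjusted p = 0.052). The list was called without control replicate 3 (adjusted p = 0.045), day 4 replicate 1 (0.046), 3 (0.048), 5 (0.049) or 6 (0.049), or day 14 replicate 1 (0.034) or 5 (0.027). Fry called the TGF-beta list with all arrays (adjusted p = 0.0062). Not called were fibroblast genes (2 of 9 rose and 1 fell in both adjustments, Vim among the former at 1.80 ± 0.23; average 0.19, but 0.02 without control replicate 1 and 0.29 without control replicate 3, median -0.09, adjusted p = 0.60) and endothelial genes (1 of 12 rose and 0 when adjusted over the list alone, Plvap at 0.76 ± 0.24 with adjusted p = 0.034; list adjusted p = 0.26). Hypoxia and glycolysis genes were not called (2 of 12 rose, 3 when adjusted over the list alone; adjusted p = 0.079), except without day 14 replicate 1 (0.046) or 5 (0.010), with Pkm at 0.91 ± 0.17. Nor were ribosomal protein genes (0 of 18; adjusted p = 0.64) or immediate early genes (3 of 13 fell, with 1 higher and 4 lower when adjusted over the list alone, Egr3 at -1.28 ± 0.27; adjusted p = 0.058). The immediate early list was called without control replicate 3 (adjusted p = 0.032), day 4 replicate 3 (0.0498) or 6 (0.049), or day 14 replicate 5 (0.017). Fry called the immediate early list with all arrays (adjusted p = 0.043) but did not call the cell cycle list (adjusted p = 0.063). Cd3e rose by 0.99 ± 0.27 (adjusted p = 0.013), while Foxp3 (-0.41 ± 0.20, adjusted p = 0.18) and Arg1 (-0.11 ± 0.20, adjusted p = 0.75) did not pass.

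Of 5033 genes, 992 changed between day 14 and control, 492 higher and 500 lower, and 429 at least 2-fold (limma). The groups did not overlap for 26.6% of genes, against 3.57% by chance. The count was 645 without control replicate 1 and 53 with median scaling, 52 higher and 1 lower, and of 52 named calls 40 passed whichever array was left out, while those for Adipoq, Cd3e, Gpnmb, Hdc, Krt14, Krt27, Lce1c, Plvap, Siglech, Stab1, Tgm2 and Thbd did not. The call of the collagen list was lost without control replicate 1 (mean 0.23, adjusted p = 0.23) or day 14 replicate 4 (adjusted p = 0.069). That of the matrix remodelling list was lost without either of these (adjusted p = 0.11 and 0.052). It was lost also without control replicate 2 (0.057) or day 14 replicate 2 (0.052).

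**Figure D2:**
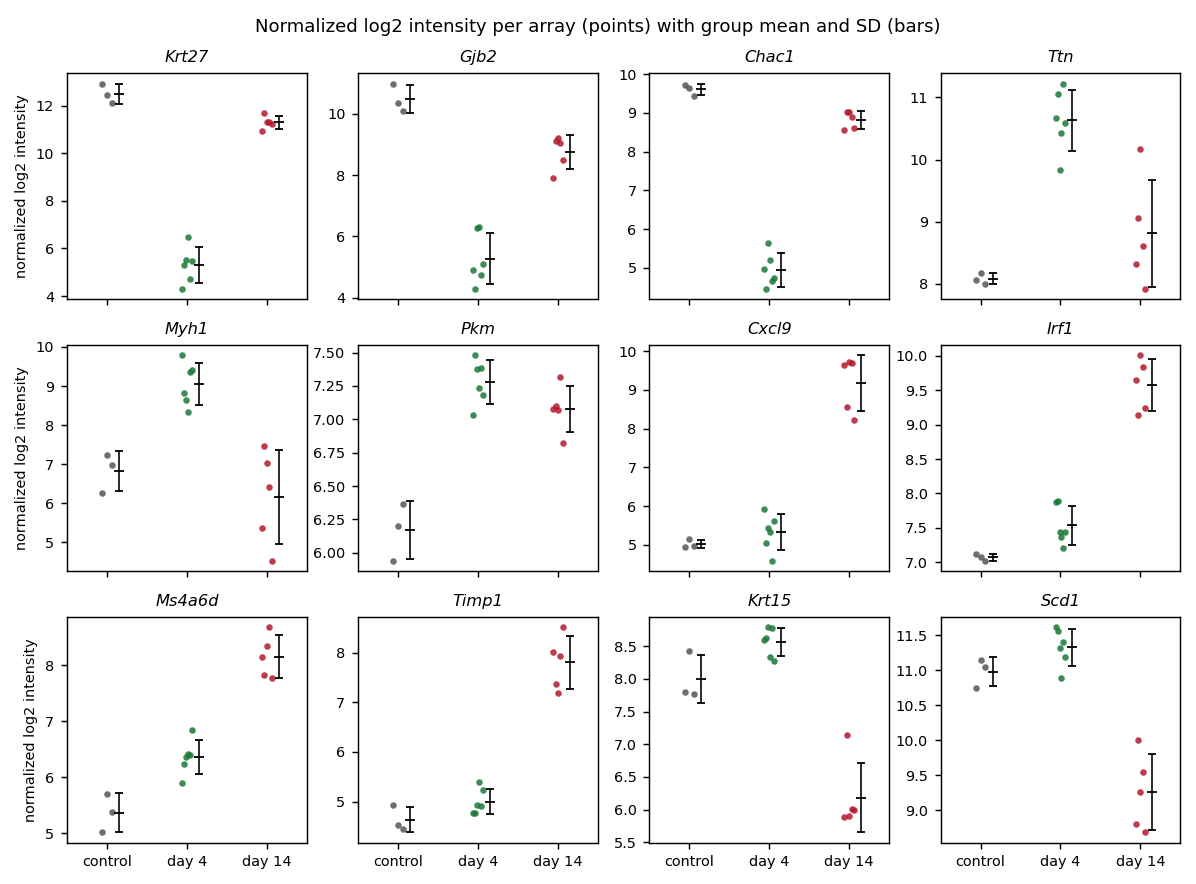
Normalized log2 intensity of 12 named genes on each array, on the vertical axis of each panel, for control, day 4 and day 14 arrays. Points are arrays and bars are group means with SD; the vertical axes differ between panels and do not start at 0, and Krt27 falls from 12.49 in control to 5.31 at day 4 and stands at 11.29 at day 14.

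The third comparison asked how the tissue at day 14 differed from that at day 4. Krt27 was 63.3-fold higher at day 14 (5.98 ± 0.29, adjusted p = 1.7e-10), at a mean log2 intensity of 11.29 ± 0.27 (SD, n = 5). Chac1 (14.7-fold, 3.87 ± 0.19) and Gjb2 (11.2-fold, 3.48 ± 0.34) rose with it. These 3 genes were near background at day 4, so their folds rest on the background correction, and without it the differences were 4.36, 2.21 and 2.05. Cxcl9 was 14.5-fold higher (3.85 ± 0.28, adjusted p = 5.1e-08). The largest falls were those of Serpina3b, a serine protease inhibitor (8.25-fold, -3.04 ± 0.31), Myh1 (7.44-fold, -2.90 ± 0.41), Cyp2e1, a cytochrome P450 (7.30-fold, -2.87 ± 0.26), and Flg2, a filaggrin family protein of the epidermis (7.14-fold, -2.84 ± 0.36). For all 8 genes each of the 5 day 14 arrays lay outside the range of the 6 day 4 arrays. The genes were picked as the largest changes among called genes whose groups did not overlap, so this holds by selection.

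Most immune lists tested were higher at day 14 than at day 4. In the interferon gamma response list 8 of 9 members rose in both adjustments, with Igtp at 2.54 ± 0.21 and Irf1 at 2.04 ± 0.18. The list averaged 1.89 (adjusted p = 1.5e-08; adjusted p = 0.12 with an estimated correlation). The monocyte and macrophage list had 8 of 12 higher and 1 lower in both adjustments. The list averaged 0.95 (adjusted p = 2.1e-05; adjusted p = 0.23 with an estimated correlation). Aif1 (2.12 ± 0.23), Ms4a6d (1.80 ± 0.20) and the complement gene C1qb (1.61 ± 0.25) rose, and the member that fell was Cd163, a hemoglobin scavenger receptor (-1.06 ± 0.22, adjusted p = 0.0014). Cd163 belongs also to the list of alternatively activated or suppressive myeloid genes, which had 1 of 10 higher and 3 lower, with 2 higher and 3 lower when adjusted over the list alone, and was not called (adjusted p = 0.52). The other 2 that fell were the lectin genes Clec10a (-0.88 ± 0.28) and Mgl2 (-0.76 ± 0.23), and the member that rose was Cd274, which encodes PD-L1 (0.99 ± 0.21). MHC class I presentation had 9 of 12 higher in both adjustments (mean 0.66, adjusted p = 6.0e-04; adjusted p = 0.23 with an estimated correlation), including the immunoproteasome genes Psmb10 (1.67 ± 0.18) and Psmb8 (1.30 ± 0.21). MHC class II presentation had 6 of 9, and 8 when adjusted over the list alone, with Lgmn at 1.67 ± 0.27. The list averaged 0.71 (adjusted p = 0.0020; adjusted p = 0.29 with an estimated correlation). Type I interferon genes had 4 of 6 in both adjustments, with Oasl2 at 2.06 ± 0.30. The list averaged 1.01 (adjusted p = 0.0024; adjusted p = 0.29 with an estimated correlation). Complement was not called (3 of 10 higher, C1qb among them, and 1 lower in both adjustments; mean 0.35, adjusted p = 0.22). Cd3e rose by 0.68 ± 0.22 (adjusted p = 0.026), and Foxp3 (-0.23 ± 0.17, adjusted p = 0.35) and Arg1 (-0.28 ± 0.16, adjusted p = 0.24) did not pass.

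Genes of proliferation and translation were higher too. Cell cycle genes rose in 10 of 14 cases, and in 11 when adjusted over the list alone, with Prc1 at 1.95 ± 0.32 and Cenpa at 1.85 ± 0.23. The list averaged 0.87 (adjusted p = 1.5e-05; adjusted p = 0.28 with an estimated correlation). Ribosomal protein genes had 9 of 18 higher and 1 lower, with 11 higher and 1 lower when adjusted over the list alone (mean 0.40, adjusted p = 0.0018; adjusted p = 0.34 with an estimated correlation), among them Rpl27 (0.98 ± 0.18) and Rpl37 (0.89 ± 0.16). Lists of skin, fat and muscle were lower beside them. All 9 adipocyte genes fell in both adjustments (mean -1.63, adjusted p = 2.3e-08; adjusted p = 0.11 with an estimated correlation), among them Adipoq (-2.19 ± 0.30), Scd1 (-2.07 ± 0.21) and Dgat2 (-1.58 ± 0.17). Of the epidermal keratinocyte list 13 of 14 fell, and 14 when adjusted over the list alone (mean -1.68, adjusted p = 3.4e-11; adjusted p = 0.11 with an estimated correlation), with Lce1c at -2.59 ± 0.26, Krt15 at -2.38 ± 0.22 and Krt14 at -0.76 ± 0.18. Skeletal muscle genes had 12 of 22 lower and 1 higher, with 13 lower and 1 higher when adjusted over the list alone (mean -1.22, adjusted p = 1.5e-05; adjusted p = 0.43 with an estimated correlation), with Ttn at -1.82 ± 0.31. The member that rose was Tpm1 (0.88 ± 0.14), and Acta1 had -0.62 ± 0.42 (adjusted p = 0.31). Fatty acid oxidation genes fell in 3 of 8 cases in both adjustments, with the muscle carnitine palmitoyltransferase gene Cpt1b at -1.24 ± 0.32. The list averaged -0.54 (adjusted p = 0.025; adjusted p = 0.39 with an estimated correlation).

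Stromal genes moved in both directions and camera called none of their lists with all arrays. Fry, which does not compare a list with other genes, called the TGF-beta list (adjusted p = 0.0029) and the matrix remodelling list (adjusted p = 0.0096). It did not call the collagen, fibroblast or endothelial lists. Collagens had 3 of 18 higher and 2 lower in both adjustments (adjusted p = 0.81), with Bgn at 1.74 ± 0.18 and Col1a1 at -1.11 ± 0.20. Fibroblast genes had 2 of 9 higher and 3 lower in both adjustments (adjusted p = 0.66), with the growth factor receptor gene Pdgfra at 1.30 ± 0.18. Matrix remodelling genes had 5 of 13 higher and 2 lower, with 5 higher and 3 lower when adjusted over the list alone (adjusted p = 0.19), and Timp1 was 6.98-fold higher (2.80 ± 0.21). TGF-beta genes had 3 of 10 higher and 1 lower in both adjustments (adjusted p = 0.068), with Inhba at 2.02 ± 0.21, and were called without day 4 replicate 1 (adjusted p = 0.030) or day 14 replicate 1 (0.046) or 5 (0.038). Endothelial genes had 2 of 12 lower, 1 when adjusted over the list alone (adjusted p = 0.29), with Mmrn2 at -0.61 ± 0.19. Hypoxia and glycolysis genes had 1 of 12 lower in both adjustments, P4ha2 (-0.84 ± 0.23; list adjusted p = 0.41).

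Between day 14 and day 4, 1450 of 5033 genes changed, 697 higher and 753 lower, and 480 at least 2-fold, 161 higher and 319 lower (limma). The groups did not overlap for 16.6% of genes, against 0.433% by chance. Median scaling, which put the median of all genes at 0.23, left 254 genes, 185 higher and 69 lower. Of 52 named calls, 48 passed whichever array was left out and those for Cd3e, Clec10a, Hdc and Siglech did not, and the call of the fatty acid oxidation list was lost without day 14 replicate 5 (mean -0.38, adjusted p = 0.051).

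Set side by side, the contrasts with control shared 137 genes called in the same direction, 61 higher and 76 lower at both times, while 29 were called in opposite directions, 238 at day 4 alone and 826 at day 14 alone. Lists that were independent would share 39.8 genes in the same direction, and unchanged groups simulated against the same controls shared 0.12 on average and 11 at most. No gene was changed in these simulations, so few calls arise by construction. Their shared counts cannot tell how many of the 137 genes come from the shared controls. Across genes, which are not independent replicates, the log2 differences at the 2 times correlated at 0.36, where the shared controls alone gave 0.65 on average in the simulations. Their covariance of 0.10 lay within the simulated range, whose mean was 0.04 and highest value 0.12. The genes lower at both times included Krt27, Gjb2 and Gpnmb, a glycoprotein of macrophages and pigment cells (-2.13 ± 0.34 at day 4 and -1.38 ± 0.35 at day 14). Those higher at both times included Ms4a6d, H2-DMb1 and Pkm. Lce1c (1.54 ± 0.30 and -1.06 ± 0.31) and Serpina3b (1.31 ± 0.36 and -1.74 ± 0.37) went in opposite directions. Without control replicate 1 neither passed at day 4 (1.26 and 0.75), Serpina3b missed the threshold there also without day 4 replicate 1, 2, 4 or 5, and Lce1c missed it at day 14 without control replicate 2 or 3 (-0.75 without the latter). The same-direction count was 28 without control replicate 1, 3 higher and 25 lower, and 61 without control replicate 2, 17 higher and 44 lower. It was 41 at 2-fold or more and 158, 43 higher and 115 lower, without background correction.

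**Figure D3:**
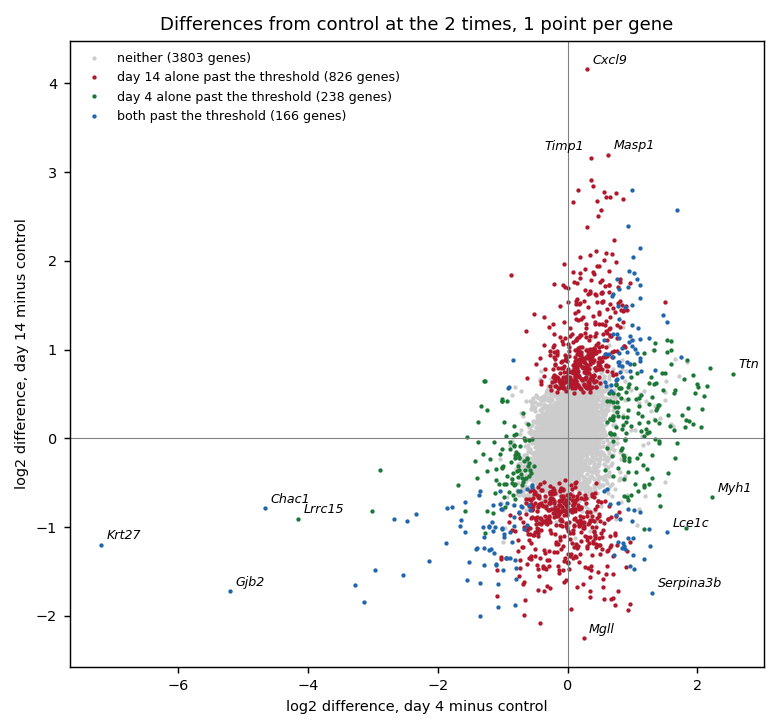
Log2 difference from control at day 4 (horizontal axis) and at day 14 (vertical axis) for 5033 genes, with colors for genes past the threshold at neither time (3803), day 14 alone (826), day 4 alone (238) or both (166). Krt27, Gjb2 and Chac1 lie far to the left, and Cxcl9, Masp1 and Timp1 lie at the top near a day 4 difference of 0.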

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

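The tests without the 2 dimmest arrays, of the epidermal list as a measure of skin, and of macrophage against stromal genes were chosen after the result was seen, and the list of growing follicle genes was drawn up after the fall of Krt27 was seen but before it was tested.

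Skeletal muscle genes were higher at day 4, with a mean log2 difference of 1.50. Acta1 stood at 12.66 at day 4 against 11.54 in control tissue, which held muscle signal as well, but its difference did not pass. The 2 dimmest arrays did not account for the higher list, since its adjusted p without them was 8.6e-11. Over the alternatives the adjusted p of the list ran from 1.1e-17 to 0.37, the latter with an estimated correlation. A candidate explanation is more skeletal muscle in the dissected day 4 tissue. The residuals of the members around their group means moved together over the 14 arrays, with a median pairwise correlation of 0.858, and 95.5% of the 22 members were positive. Muscle genes would move together wherever the muscle content varies between arrays. This therefore cannot tell more muscle at day 4 from a response of muscle. The 221 genes outside the list that were higher at day 4 did not follow the muscle mean as a set. Their residuals correlated with those of the muscle mean at a median of -0.0167, near the 0.0304 of all other genes. More muscle is not excluded for the 40 of them that exceeded 0.5. The muscle mean spread most at day 14 (SD 1.10, against 0.44 at day 4), so these correlations say less about day 4. A response of muscle to the inoculation was not tested and stays open, because the way the tissue was dissected is not given in the sources used here.

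Krt27, the only measured member of the hair follicle list, was lower at day 4. Less skin in the day 4 tissue would lower epidermal genes too, but the mean difference of the epidermal keratinocyte list was 0.352 ± 0.192 (SE over 14 members). It was 0.189 without control replicate 1, no larger than that error, and 0.0993 with median scaling, so the values argue against a fall of skin large enough to explain Krt27 but not against a small one. A candidate explanation is hair follicles in another phase of the growth cycle: of a further list of 51 genes of the growing follicle, without the genes already seen to fall, 12 were measured, 6 fell and 0 rose (mean -0.67, camera p = 1.6e-07, and p = 0.0011 with an estimated correlation). The brightest were Krt17, which went from 12.93 to 11.76 (-1.16 ± 0.17), and Sox9, from 10.91 to 10.17 (-0.74 ± 0.18); both are also made elsewhere in the epidermis or its appendages, and 1 of the 12, Gata3, is in another list. A smaller share of follicles in the tissue would lower these genes too, so the list cannot tell it from another phase. Whether a difference in phase, if there was one, came from the inoculation, the date of sampling or the choice of site was not tested.

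Interferon gamma response and macrophage genes were higher at day 14. The 2 dimmest arrays were day 14 replicate 5 and day 4 replicate 2. The former had the lowest macrophage mean of the day 14 arrays (1.15), and its interferon gamma mean (1.91) lay below the group mean of 2.36. It therefore did not raise the lists, and leaving it out could hardly weaken them. Without both arrays the larger adjusted camera p of the lists was 1.6e-09. Over the alternatives the largest was 0.057 for each list, with an estimated correlation. If a lower share of skin and fat raised every other cell type alike, fibroblast and endothelial genes would rise as much as macrophage genes. Macrophage members instead rose by 1.31 ± 0.288 (SE over members) more than fibroblast and endothelial members (means 1.49 and 0.186, 12 and 21 members). The members are not independent, so this error does not measure the spread between arrays. Leaving out each control or day 14 array in turn gave differences of 1.23 to 1.38. Without control replicate 1 the fibroblast and endothelial mean was 0.0871 and the difference 1.31. The values argue against the 2 dimmest arrays as the cause. They also argue against a shift that raised every other cell type alike, but only for the macrophage members. The interferon gamma genes were left out of that comparison. Skin and fat hold fibroblasts and vessels too, so a loss of skin and fat could hold these lists down. A lower share of skin and fat is therefore not excluded. Effects of the chip, the dissection or the site of the control tissue could not be tested. More macrophages and an interferon response in the tissue at day 14 are a hypothesis found on these arrays and were not tested. Which cells carried the signal, and how much came from tumor cells, was not tested.

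In 256 groups of arrays tested for a value far from the others, over named genes, lists and the share of detected probes, 12 had such an array, where chance gives 12.8. Of these, 7 were in day 14 replicate 2, the array with the most detected probes. Its log2 intensity was low for H2-T23 (6.95, the other day 14 arrays 7.72 to 7.90), Eif2ak2 (7.02, others 8.02 to 8.41) and Masp1 (7.67, others 8.47 to 8.74). It was high for Casp14 (7.85, others 7.06 to 7.22), Krt15 (7.14, others 5.88 to 6.01), Dgat2 (5.63, others 4.80 to 5.00) and Gata3 (7.23, others 6.50 to 6.69). Timp3 was low in day 14 replicate 5 (6.42, others 7.56 to 7.94). Among day 4 arrays, Mmrn2 was high in replicate 1 (6.23, others 5.73 to 5.88), Egr2 was high in replicate 3 (7.89, others 7.08 to 7.30), Gpnmb was low in replicate 5 (5.90, others 6.72 to 7.01) and Bcl11b was low in replicate 6 (6.75, others 7.67 to 7.99).

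The effect of day 14 differed from that of day 4 in 11 lists by camera on day 14 minus day 4. Their mean differences were 1.89 for interferon gamma response, 1.01 for type I interferon response, 0.95 for monocyte and macrophage, 0.87 for cell cycle, 0.71 for MHC class II presentation, 0.66 for MHC class I presentation and 0.40 for ribosomal protein genes. They were -1.68 for epidermal keratinocyte, -1.63 for adipocyte, -1.22 for skeletal muscle and -0.54 for fatty acid oxidation genes. With an estimated correlation 0 of these 11 differences passed. Lce1c differed by -2.59 between the times (adjusted p = 9.4e-07) and Serpina3b by -3.04 (adjusted p = 1.1e-06), each past the threshold on opposite sides of control with all arrays. Without control replicate 1 neither passed at day 4 (1.26 and 0.75), Serpina3b did not pass there without day 4 replicate 1, 2, 4 or 5 either, and Lce1c did not pass at day 14 without control replicate 2 or 3 (-0.75 without the latter).

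Among probes without a gene name, 9 were detected on all 6 day 4 arrays and on 0 of 3 control arrays. The same held for 62 probes on all 5 day 14 arrays.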

How the results depend on the processing

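Fits without the 2 dimmest arrays, with the share of detected probes as a covariate, or scaled over probes detected on all arrays were chosen after seeing the data; all other alternatives were set beforehand. No called result reversed. For day 4 against control (404 genes, 234 higher and 170 lower), median scaling left 20, all lower, and put the median of all genes at -0.16, against 0.02 before. Cyclic loess gave 624 and array weights 752. The authors' values gave 475, 183 higher and 292 lower. Leaving out arrays gave 93 (without control replicate 1) to 556 (without day 14 replicate 5). It gave 184 without control replicate 2, and 255 without day 4 replicate 1 or 5. For day 14 against control (992), median scaling left 53, 52 higher and 1 lower, and leaving out arrays gave 645 (without control replicate 1) to 1111 (without day 14 replicate 2). For day 14 against day 4 (1450, 697 higher and 753 lower), median scaling left 254, 185 higher and 69 lower, with the median of all genes at 0.23, against 0.02 before. Median scaling kept only calls that the quantile fit had also made. The replicate block, with the replicate number as a factor, gave 248 genes for day 4, 725 for day 14 and 1377 for day 14 against day 4. Nothing in the labels says that the numbers pair the arrays. Residuals of 11 pairs with the same number correlated at -0.171 to 0.179, and 1 pair exceeded 0.1. Pairs with different numbers were not set beside them, so these values do not exclude a pairing. Counts at 2-fold or more were 195, 429 and 480, and counts of probes in place of genes 707 (273 higher and 434 lower, the reverse of the balance for genes), 1800 (797 and 1003) and 2542 (1264 and 1278). Without the 2 dimmest arrays the counts were 560, 1101 and 1347, with the covariate 541, 1158 and 1680, and with scaling over probes detected on all arrays 378, 963 and 1323. Camera called 11 lists in each comparison at the preset correlation, and 0, 0 and 0 with an estimated correlation. Fry called 0, 12 and 13 lists, among them some that camera had not called. Leave-one-out fits changed no count of lists by 1.5 times. At an unadjusted p under 0.05, 1114, 1581 and 1926 genes passed. Of 137 genes called in the same direction at both times, 61 higher and 76 lower, 41 passed at 2-fold or more. Leaving out arrays gave 28 (3 higher and 25 lower, without control replicate 1) to 191 (without day 14 replicate 5), with 61 (17 higher and 44 lower) without control replicate 2. Without background correction there were 158, 43 higher and 115 lower. Of 192 results for named genes, 141 were called; 89 calls were lost with median scaling, 33 without control replicate 1, 24 with the replicate block and 14 with the authors' values. At a detection p under 0.01 the median share of detected probes was 18.1%, against 24.4% at 0.05. Median scaling used the median of all 45281 probes, of which at most 30.6% were detected on any array. The same scaling over probes detected on all arrays gave 378, 963 and 1323 genes, so the drop goes with the probes used for scaling. The causes of the other differences were not tested, except that leaving out arrays and a higher threshold leave fewer arrays or genes by construction. The slide could not be used as a block, since the files name no chip, and lifting the filter on dim probes removed no tested gene, so it says nothing. Signal over background limits the folds of dim genes: the difference of Krt27 at day 4 ranged from -7.42 to -5.53 over 28 alternatives.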

Other observations

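No test in this part was chosen after the result was seen, but Stab1, Tgm2 and, at day 14, Gpnmb are named here after their values were seen. Lists with fewer than 5 measured members were not tested as sets, and their genes give a partial view of lymphoid and other immune cells. Of 4 T cell genes, Cd3e, a chain of the T cell receptor complex, rose at day 14 and Bcl11b, a factor of T cells that skin cells make too, fell (-1.27 ± 0.29, adjusted p = 0.0043). Neither cytotoxic gene passed: Cd8b1 had -0.12 ± 0.18 at day 4 (adjusted p = 0.76) and the perforin gene Prf1 -0.51 ± 0.29 at day 14 (adjusted p = 0.25). Cd274, which encodes the checkpoint ligand PD-L1, rose 2.61-fold at day 14 (1.38 ± 0.25, adjusted p = 7.4e-04), and the costimulator gene Cd86 had 0.25 ± 0.29 (adjusted p = 0.59). Of 4 measured chemokine and cytokine genes 3 rose at day 14, with the monocyte-attracting Ccl8 at 1.94 ± 0.22 (adjusted p = 1.5e-05). Siglech, a receptor of plasmacytoid dendritic cells, rose by 1.76 ± 0.46 (adjusted p = 0.010), but not without control replicate 1 or control replicate 2. Hdc, the histamine-forming enzyme of mast cells, rose by 0.99 ± 0.25 (adjusted p = 0.0098), but not without control replicate 1. Ltf, the lactoferrin gene of neutrophil granules and glands, fell at both times (-1.52 ± 0.34 at day 4 and -1.39 ± 0.35 at day 14), and Ccl11, the eotaxin gene, did not pass (0.48 ± 0.23 at day 14, adjusted p = 0.17). Gata3, a factor of T helper cells and of skin and hair, fell by 1.72 ± 0.22 at day 14. At day 4, 1 of 2 measured regulatory T cell genes, Itgae, and 1 of 2 measured T helper genes, Bcl6, were called higher. Neither call held without control replicate 1. Ccl21a, a chemokine of lymphatic vessels and lymph node stroma, was lower at day 14 than at day 4 (-2.05 ± 0.31, adjusted p = 6.5e-05).

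Within the list of alternatively activated or suppressive myeloid genes, members went apart at both times, and the list was not called with all arrays (adjusted p = 0.077 at day 4, 0.020 without day 4 replicate 3, and 0.59 at day 14). At day 4, 2 of 10 rose and 1 fell, with 4 and 1 when adjusted over the list alone. Those that rose were the scavenger receptor gene Stab1 (1.47 ± 0.37, with its other probe at -0.75) and the transglutaminase gene Tgm2 (1.12 ± 0.30). The member that fell was Gpnmb. At day 14, 3 rose, Stab1 (1.39 ± 0.38), Tgm2 (1.12 ± 0.31) and Cd274, and Gpnmb fell. Of oxidative phosphorylation genes 0 of 22 passed at day 4 (adjusted p = 0.99) and 0 at day 14 (adjusted p = 0.34). Between the times 2 rose, and 1 when adjusted over the list alone (adjusted p = 0.41), with the cytochrome oxidase subunit gene Cox5b at 0.57 ± 0.15. Fatty acid oxidation genes had 0 of 8 passing against control at either time (adjusted p = 0.31 and 0.17). Egr2, a factor of Schwann cells and of the early response to growth factors, fell by 1.42 ± 0.22 at day 14, and the thrombomodulin gene Thbd fell by 0.80 ± 0.26 (adjusted p = 0.036), but the latter not without any of 6 single arrays.

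Other splits of the arrays were refitted to set their gene counts beside the real ones. For day 4 and control, 1 of the 84 splits, the real one, gave as many genes as the real 443, and the highest of the others gave 0. For day 14 and control it was 1 of 56, with 949 genes and 7 at most in the others. For day 14 and day 4 it was 1 of 100 splits drawn from 462, with 1335 genes and 688 at most in the others; the split with 688 differed from the real split by a single day 4 array placed with the day 14 arrays. These fits used the 2 groups compared. No other split reached the real count, which makes chance less likely but does not exclude it. The splits are few, and the others mix arrays of the 2 groups, which widens the spread and lowers their counts.

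Over all 14916 probes kept, 273 were higher and 434 lower at day 4, 797 higher and 1003 lower at day 14, and 1264 higher and 1278 lower at day 14 against day 4. Among the 8833 of these without a gene name here, the counts were 59 higher and 259 lower, 268 higher and 451 lower, and 513 higher and 451 lower. Among unnamed probes, 134 were detected on all control arrays and no day 4 array, 38 on all control arrays and no day 14 array, 76 on all day 14 arrays and no day 4 array, and 6 on all day 4 arrays and no day 14 array.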
